A study of Mus musculus with 8 samples.

How the data were processed

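The data are RNA sequencing libraries of nephron progenitor cells sorted by GFP from mouse kidneys at embryonic day 17.5, with 4 libraries of cells heterozygous and 4 of cells homozygous for the deleted Vhl allele. Each library was placed in its group by the genotype in its labels. Libraries were made from polyadenylated RNA with a stranded kit, per the labels' protocols. Per the submitters' processing notes, the authors used STAR 2.5.3a, DESeq2 1.18.1 and the mm10 assembly. The read counter, the gene annotation and whether the counting used strand are not given in the sources used here.

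The deposited table has 20254 genes and a signal per library, which per the file headers and the values themselves is read counts per gene divided by size factors. The values show that this division was applied a second time with the 8 size factors recycled down the genes, in the order the genes had before they were sorted, and that the result was rounded. Both steps could be undone: whole reads that rebuild the deposited mean of a gene within a relative tolerance of 1e-09 were found for 20254 of 20254 genes. Of 11635 genes with at least 100 in each library, 0 could be rebuilt without the second division and 0 with its factors in another order. The second factor lies between 0.872 and 1.078. It differs between the libraries of a group by an SD of 0.061 (log2) in odd positions of the cycle and 0.135 in even ones, and it averages out between the groups. The same deposited table holds the authors' log2 fold changes with their standard errors, a Wald score and p-values with adjusted p-values, from DESeq2 per the file headers. The authors' log2 values and p-values were used as an alternative, and the deposited score was not used. No column of per-sample values was left out.

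The analysis used the values divided once by the size factors (normalised reads). Genes with at least 10 normalised reads in at least 4 libraries were tested, which left 15381. Values were put on the scale log2(value + 1) and compared between the groups with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level and are robust to outlying genes, in 1 fit of all 8 libraries with no covariate. p-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Means and SDs are of normalised reads, while fold changes come from the fit. A count model with another normalisation had been planned, and it was replaced because the deposited values are a signal and not counts. It could have been run on the recovered whole reads but was not, while limma-voom was run on them as an alternative. The Vhl level also had a two-sided exact permutation test of its log2 values.

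Choices made before the data were examined were the groups, the comparison, the gene lists, the rule for named genes and a first set of other settings. The named genes are Vhl, Hif1a, Epas1, Hif3a and Arnt; the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 on the log2 CPM scale and no overlap between the groups; up to 4 tested members of each list with the smallest adjusted p; and Six2, Cited1, Wnt4, Lhx1, Pax8, Vegfa, Slc2a1, Pdk1 and Ldha. This gave 113 genes. The values of a few of them are not reported here. Other genes are said to have been named after their values were seen. Of the 22 lists, 19 had at least 5 tested members and were compared with the other genes by camera on the same values with a preset correlation of 0.01 between genes, adjusted over the 19 lists. This was repeated with an estimated correlation and with fry, which asks whether a list moves one way on balance. By camera 4 lists were called, of which 2 were called with an estimated correlation, and fry called 2. A mixed form of fry, which asks whether members move in either direction, called these 2 as well. It also called the citrate cycle (adjusted p = 0.0123), fatty acid oxidation (0.004), nephron progenitors (0.0004) and early nephron differentiation (0.0176). The canonical Wnt response (0.00533), p53 targets (9.36e-06) and the integrated stress response (2.69e-08) were called by it too, and the other lists were not. Neither form of fry compares a list with the other genes, and the mixed form can give a call through a few changed members. Each list was also counted by its called members, and again adjusted over the list alone.

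The totals of the recovered reads were 41.6, 43.0, 41.2 and 43.9 M (mega) in controls 1 to 4 and 45.1, 46.5, 41.3 and 37.3 M in mutants 1 to 4. Fold changes are therefore limited in precision mainly by the spread between libraries, and by counting for genes near the minimum. The 10 most abundant genes took between 4.37% and 5.07% of the reads, and Rn45s, a ribosomal RNA gene, between 0.32% and 0.76%. Pearson correlations across genes were between 0.983 and 0.993 for libraries of the same group and between 0.977 and 0.988 across the groups. Control 3 correlated best with mutant 2 (0.986), above the other controls (0.983 to 0.985). Each pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom between 12.4 and 38.0, so none was treated as a library deposited again. This does not show that they are separate biological samples. The first principal component held 34.1% of the variance and the second 28.5%.

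The procedure was tested on simulated counts drawn from the control means and the size factors of these libraries, with 200 genes changed. The spread was a set function of the mean and not estimated from these libraries, and genes varied independently. The rates below hold for that setting and may differ for these data. Among 66 genes at each size, 78.8% of those changed 1.5-fold, 92.4% of those changed 2-fold and 100% of those changed 4-fold were called, and 8 of 15097 unchanged genes were called. With no gene changed, 0 genes were called. Of 20 simulated lists, camera called the 1 that had been shifted and 0 others.

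Coordinates are 1-based and come from GENCODE release M21, an annotation of the same assembly, matched by the Ensembl identifiers of the table. Of the 113 named genes, 48 overlap a gene on the other strand and 24 one on the same strand, so their values are uncertain to the extent that reads were shared. Alternatives to the scaling, the filter, the added constant, the test, the design and the set of libraries were run, and their effect is given in the closing section. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 built the tables, and matplotlib 3.10.9 drew the figures.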

Results

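RNA sequencing measured polyadenylated transcripts in nephron progenitor cells of the mouse embryonic kidney. These are the self-renewing cap mesenchyme cells that give rise to the epithelium of the nephron. They were sorted at embryonic day 17.5 by the green fluorescence of a transgene that expresses a GFP and Cre recombinase fusion under Six2, a transcription factor of these cells. In 4 libraries the sorted cells were heterozygous for the Cre-deleted Vhl allele (controls 1 to 4), and in 4 libraries they were homozygous for it (mutants 1 to 4). Vhl encodes the subunit of a ubiquitin ligase that recognises the alpha subunits of hypoxia-inducible factor (HIF) and marks them for degradation. The series asks how loss of Vhl in these cells bears on their metabolism and on their differentiation. The comparison of mutant with control libraries addresses that question only for transcripts of the sorted cells. The libraries held between 37252683 and 46515762 reads assigned to genes, and 15381 genes were tested. Levels are given as normalised reads, and log2 fold changes are mutant minus control on the scale of log2(normalised reads + 1), which understates changes of genes with few reads. The labels do not say that the libraries of a group came from separate animals or pools, so the p-values measure the spread between these samples, which may be partly technical.

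Vhl itself was lower in each mutant library than in each control library. The gene lies on chromosome 6 from 113623959 to 113631633 of the mm10 assembly, and no other annotated gene overlaps it. Its level was 1225 ± 107 normalised reads (SD, n = 4) in controls and 318 ± 23.2 (SD, n = 4) in mutants, which is 26% of the control level. The highest mutant value was 335.9 and the lowest control value was 1134. The level fell by 1.94 on the log2 scale (SE 0.08, limma adjusted p = 4.22e-08), and a two-sided exact permutation test over 70 relabellings gave p = 0.0286, the smallest value that 4 against 4 libraries allow. The reads were counted over the whole gene, so they do not separate its deleted part from the rest.

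Of the genes for the HIF subunits, Hif1a and Hif3a fell, and Epas1 and Arnt were not called. Hif1a fell by 0.41 on the log2 scale (SE 0.07, adjusted p = 0.00436), from 7463 ± 613 to 5601 ± 391 normalised reads (SD, n = 4 each). Hif3a fell by 0.26 (adjusted p = 0.0468), a call that held only in the fit without control 4 when 1 library was left out, with an adjusted p of up to 0.106 in the others. Epas1, which encodes HIF-2 alpha, was at 335 ± 106 and 297 ± 50.8 (SD, n = 4 each, adjusted p = 0.803). Arnt, which encodes the beta subunit, was at 3859 ± 133 and 3617 ± 110 (SD, n = 4 each, adjusted p = 0.305).

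Across all genes, 1297 of 15381 changed at an adjusted p under 0.05 in limma, 831 of them higher and 466 lower in mutants. Large changes were almost all rises: of the 250 called genes with an absolute log2 fold change of at least 1, 230 rose and 20 fell. The largest rise was that of Adamts13, which encodes the protease that cleaves von Willebrand factor. It rose 51.3-fold, from 46.5 ± 3.68 to 2441 ± 278 normalised reads (SD, n = 4 each, adjusted p = 7.9e-11). The authors' deposited table calls 1888 of 15144 genes, of which 1277 were called here too, 0 of them with the opposite sign. The number of called genes was 771 without mutant 4 and 815 without control 4, and fallen genes numbered 256, 230, 279 and 232 without control 2, control 4, mutant 3 and mutant 4. It was 697 with the deposited values left as they are, 2488 with library quality weights, 141 when tested against a fold of 1.5, 754 without control 3 and mutant 2, and 654 without control 2 and mutant 2, the libraries with almost no Xist reads; the pairs left out and the deposited values were chosen after seeing the data.

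**Figure D1:**
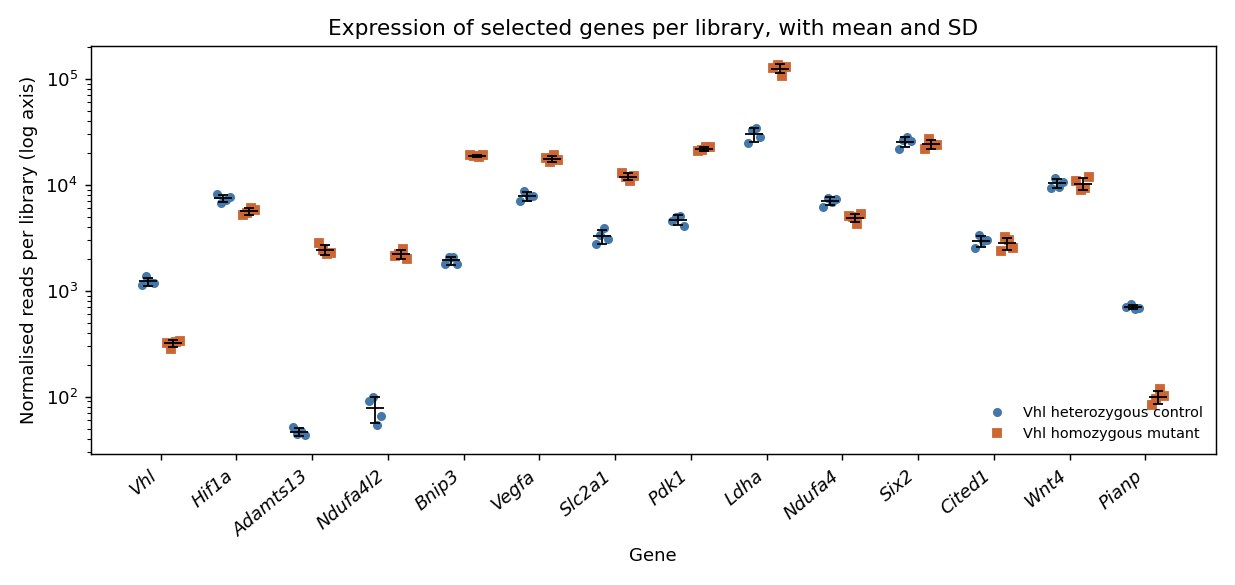
Normalised reads (log axis) of 14 genes in each of the 4 control libraries (circles) and 4 mutant libraries (squares), with the mean and SD of each group in black. Vhl is at most 335.9 in the mutants and at least 1134 in the controls, Adamts13 rose 51.3-fold, and the groups overlap for Six2, Cited1 and Wnt4.

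The other genes of the 12 largest rises rose between 12.1-fold and 28.8-fold. Ndufa4l2, a paralog of the respiratory chain subunit Ndufa4, rose 28.8-fold, from 77.5 ± 21.3 to 2202 ± 199 (SD, n = 4 each, adjusted p = 2.47e-08). Cox4i2, the alternative isoform of subunit 4 of cytochrome c oxidase, rose 14.9-fold, and Mgarp, which encodes a mitochondrial protein, rose 24.0-fold. Slc2a3, a glucose transporter, rose 12.6-fold to 4124 ± 162 (SD, n = 4). Stc2, a secreted glycoprotein hormone, rose 21.6-fold, and Adm2, a peptide of the adrenomedullin family, rose 22.4-fold. The gel-forming mucin Muc2 rose 21.9-fold to 517 ± 84.0 (SD, n = 4), and the mucin-like Fcgbp rose 12.3-fold. Ciart, a repressor of the circadian clock, rose 13.2-fold, Fam184b 18.4-fold and Rgs11, a regulator of G protein signalling, 12.1-fold. The adjusted p of each of these was at most 1.88e-07, and each kept its call when any 1 library was left out. How the counting used strand is not given in the sources used here, so the values of Ndufa4l2 (with Shmt2), Fam184b, Ciart and Rgs11, which overlap a gene on the other strand, are uncertain.

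Falls were smaller. Pianp, which encodes a neuronal membrane protein, fell by 2.82 on the log2 scale, from 705 ± 32.4 to 99.7 ± 14.1 normalised reads (SD, n = 4 each, adjusted p = 1.97e-08). The muscle alpha-actinin Actn3 fell by 1.44 (adjusted p = 4.17e-04), Lrrc4b fell by 1.40 and Dpysl4 fell by 1.20. Rims2, a scaffold of the presynaptic active zone, fell from 173 ± 20.7 to 75.6 ± 6.78 (SD, n = 4 each), and Slc6a13, a GABA transporter, fell by 1.15. Scrn1 and Cbr2 each fell by 1.15, and Sarm1, an enzyme that cleaves NAD, fell by 1.02. Igf2bp3, an RNA-binding protein of fetal tissues, fell by 1.13, from 1862 ± 317 to 853 ± 169 (SD, n = 4 each, adjusted p = 0.00385). Rims2, Slc6a13, Scrn1 and Igf2bp3 overlap a gene on the other strand.

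Known HIF target genes outside glycolysis rose as a group. Of 28 tested members, 23 rose, 0 fell and 5 were not called by limma. At an unadjusted p under 0.05, 25 lay higher and 0 lower, the authors' deposited table called 23 and 0, and adjusted over the list alone 25 rose. The median log2 fold change was 1.44, and the list stood above the other genes (camera adjusted p = 1.02e-37, adjusted p = 3.17e-04 with an estimated correlation). Bnip3, a mitophagy receptor, rose 9.74-fold, from 1930 ± 168 to 18747 ± 392 (SD, n = 4 each, adjusted p = 7.9e-11). The collagen prolyl hydroxylase P4ha2 rose 5.08-fold and the mitochondrial protein Fam162a 3.87-fold. Vegfa, the endothelial growth factor, rose 2.27-fold, from 7793 ± 748 to 17644 ± 1178 (SD, n = 4 each, adjusted p = 1.52e-06). Members without a call, named here after their values were seen, were Car9 (log2 fold change 0.40), Car12 (-0.12), Lox (0.28), Edn1 (-0.66) and Cited2 (0.27). Bnip3 and Fam162a overlap a gene on the other strand.

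Glycolytic genes rose with them. Of 22 tested members 19 rose, 0 fell and 3 were not called. At an unadjusted p under 0.05, 19 lay higher and 1 lower, the authors' deposited table called 19 and 0, and adjusted over the list alone 19 rose and 1 fell. The median log2 fold change was 1.86 (camera adjusted p = 1.05e-33, adjusted p = 0.0275 with an estimated correlation). Ldha, which converts pyruvate to lactate, rose 4.18-fold, from 29968 ± 4360 to 124818 ± 11897 normalised reads (SD, n = 4 each, adjusted p = 2.65e-07). Pdk1, the kinase that inhibits pyruvate dehydrogenase, rose 4.68-fold to 21804 ± 1025 (SD, n = 4), and the glucose transporter Slc2a1 rose 3.66-fold to 11911 ± 879 (SD, n = 4). The phosphofructokinase Pfkp rose 11.9-fold and Pfkfb3, which makes its activator fructose bisphosphate, rose 8.67-fold. The members without a call, named after their values were seen, were Pfkm (log2 fold change -0.05), Eno2 (-0.40) and Pfkfb4 (-0.18). The count of Eno1, 7.62 normalised reads on average in controls, is uncertain, because its near-identical copy Eno1b carried most of the reads and rose from 36084 ± 4582 to 81861 ± 8076 (SD, n = 4 each), as are those of Pfkp and Pfkfb3, which overlap genes on the other strand.

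**Figure D2:**
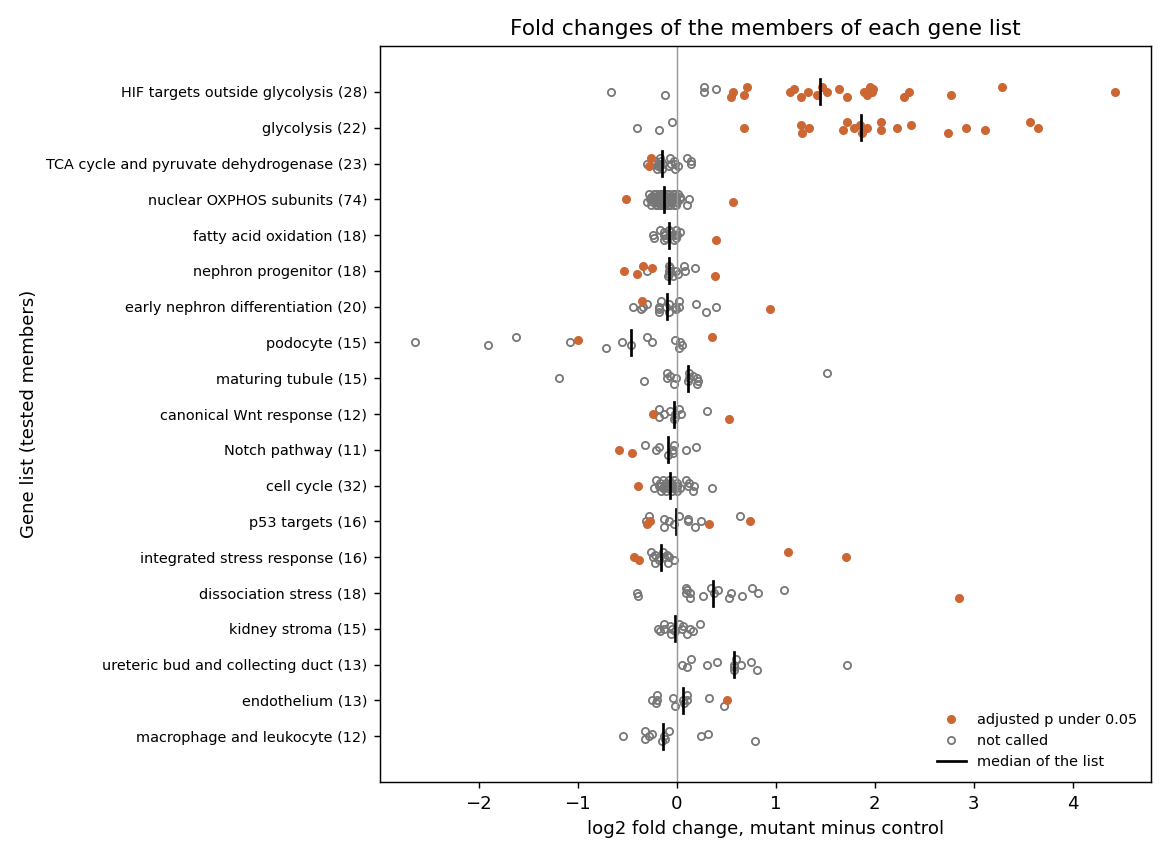
log2 fold change (mutant minus control) of each tested member of 19 gene lists, with called members filled, others open, and the median of each list as a black bar. The medians of the HIF targets (1.44) and of glycolysis (1.86) lie apart from those of the other lists.

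Single genes of mitochondrial oxidation changed, while most members of these lists were not called. Ndufa4, a subunit of cytochrome c oxidase, fell by 0.52 on the log2 scale, from 7006 ± 629 to 4901 ± 428 (SD, n = 4 each, adjusted p = 0.00232). Ndufv3, a subunit of complex I, rose 1.48-fold, from 1914 ± 153 to 2834 ± 170 (SD, n = 4 each, adjusted p = 3.54e-04). They were the called members among 74 nuclear-encoded subunits of oxidative phosphorylation, 72 of which were not called. With no adjustment, 1 lay higher and 21 lower at a p under 0.05, the authors' deposited table called 1 risen and 6 fallen, and adjusted over the list alone 1 rose and 1 fell. The median was -0.13, and camera placed the list below the other genes (adjusted p = 1.39e-06), but not with an estimated correlation (adjusted p = 0.895). Of 23 genes of the citrate cycle and pyruvate dehydrogenase, 0 rose, 2 fell and 21 were not called by limma. At an unadjusted p under 0.05, 0 lay higher and 11 lower, and the authors' deposited table called 0 risen and 9 fallen. Adjusted over the list alone, 9 fell. The median was -0.15 (camera adjusted p = 0.00118, adjusted p = 0.895 with an estimated correlation). Idh2 fell by 0.28 (adjusted p = 0.0354) and the citrate synthase gene Cs fell by 0.26 (adjusted p = 0.0499). Both calls held only without control 1 or mutant 1 when 1 library was left out, with adjusted p up to 0.108 and 0.14. Pdha1, a subunit of pyruvate dehydrogenase, was at 5118 ± 197 and 4467 ± 219 (SD, n = 4 each, adjusted p = 0.0534), and Fh1 had an adjusted p of 0.0565.

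Of 18 genes of fatty acid oxidation 1 rose, 0 fell and 17 were not called by limma. At an unadjusted p under 0.05, 1 lay higher and 4 lower, the authors' deposited table called 1 and 2, and adjusted over the list alone 1 rose and 2 fell. The risen gene, the thiolase Acaa2, went from 6800 ± 529 to 8987 ± 819 (SD, n = 4 each, adjusted p = 0.00805). Hadhb, Eci1 and Acadl were not called (adjusted p = 0.0533, 0.073 and 0.142). The list's camera adjusted p was 0.0863, and it was 0.0309 without control 3 and 0.0276 without mutant 1, and the full fit gave an adjusted p of 0.895 with an estimated correlation. The 13 mitochondrially encoded messenger RNAs are not analysed here.

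Among nephron progenitor genes a few members changed, and Six2 and Cited1 were not called. The sort by GFP under Six2 partly selected for Six2 expression, and cells without GFP were not sorted. These levels therefore do not show whether the number of progenitors or the share that differentiated changed. Six2 was at 25540 ± 2806 normalised reads in controls and 24101 ± 2213 in mutants (SD, n = 4 each, adjusted p = 0.647), and Cited1 at 2951 ± 349 and 2792 ± 384 (SD, n = 4 each, adjusted p = 0.706). The homeobox gene Meox1 fell by 0.40 on the log2 scale, from 2141 ± 131 to 1622 ± 122 (SD, n = 4 each, adjusted p = 0.00396). Gdnf, the ligand that draws the ureteric bud into the mesenchyme, rose 1.31-fold, from 4627 ± 510 to 6040 ± 261 (SD, n = 4 each, adjusted p = 0.0101). Tmem100 fell by 0.53 (adjusted p = 0.0205) and Dpf3 fell by 0.34 (adjusted p = 0.0213). Tmem100 lost its call without control 2, control 4 or mutant 4 (adjusted p up to 0.0708), and Dpf3 without control 3, control 4 or mutant 4 (up to 0.0771). In all, 1 of 18 members rose, 4 fell and 13 were not called, with the same numbers adjusted over the list alone. The fourth fallen member was Osr1 (fell by 0.25, adjusted p = 0.0404), named after its values were seen. The camera adjusted p was 0.119, and it was 0.0362 without mutant 3, and the full fit gave an adjusted p of 0.895 with an estimated correlation. Mixed fry, which allows members to move either way and can give a call through a few members, gave an adjusted p of 0.0004.

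Genes of early nephron differentiation gave no call in 1 direction as a group in the fit of all libraries. Mixed fry, which allows members to move either way and can give a call through a few members, gave an adjusted p of 0.0176. Of 20 tested members 1 rose, 1 fell and 18 were not called, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.56, and 0.0144 without control 3, with an adjusted p of 0.946 for all libraries with an estimated correlation). Greb1, an oestrogen-responsive gene, rose 1.92-fold, from 1264 ± 91.5 to 2433 ± 247 (SD, n = 4 each, adjusted p = 2.12e-05). The cadherin gene Cdh6 fell by 0.35 (adjusted p = 0.0483), a call lost without control 1, control 2, control 4, mutant 2 or mutant 4 (adjusted p up to 0.152). Wnt4, a signal that acts in the conversion of progenitors to epithelium, was at 10308 ± 1009 and 10283 ± 1346 (SD, n = 4 each, adjusted p = 0.975). Lhx1 was at 692 ± 180 and 611 ± 155 (SD, n = 4 each, adjusted p = 0.752), and Pax8 at 6876 ± 177 and 6550 ± 558 (SD, n = 4 each, adjusted p = 0.542). Fgf8 and Sfrp2 had adjusted p of 0.0646 and 0.0828. The median deviation of the list from the group mean was -0.56 in control 3 and -0.35 in mutant 2, and between -0.01 and 0.23 in the other libraries.

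In the podocyte list 1 of 15 tested members rose, 1 fell and 13 were not called, with the same numbers adjusted over the list alone. Plce1 rose 1.28-fold (adjusted p = 0.0215), a call lost without control 4, mutant 3 or mutant 4 (adjusted p up to 0.0779). Cdkn1c and Ptpro had adjusted p of 0.174 and 0.179. The median log2 fold change was -0.46 (camera adjusted p = 0.0863), and camera called the list without control 3, mutant 1 or mutant 3 (adjusted p = 7.97e-04, 0.0276 and 0.0362). With an estimated correlation the fit of all libraries gave an adjusted p of 0.895. The median deviation of the list was 0.73 in control 2 and -0.75 in control 3.

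Markers of other kidney cell types other than podocytes gave 1 call in 6 lists. Plvap, which encodes a protein of endothelial diaphragms, rose 1.43-fold, from 519 ± 60.6 to 741 ± 92.8 (SD, n = 4 each, adjusted p = 0.0135), with an adjusted p of 0.0534 without mutant 4. It was the called member of 13 in the endothelial list, also when adjusted over the list alone, and Egfl7, Tek and Sox17 were not called (adjusted p = 0.234, 0.332 and 0.593; camera adjusted p = 0.748). By limma 0 members changed among 15 of the maturing tubule (camera adjusted p = 0.884, and 0.0376 in the other direction without control 3, with an adjusted p of 0.965 for all libraries with an estimated correlation), 15 of kidney stroma (0.748) and 12 of macrophages and leukocytes (0.668). The same was true at an unadjusted p under 0.05 and in the authors' deposited table. In those lists Slc12a3, a salt transporter of the distal tubule, was at 69.2 ± 44.2 and 188 ± 129 (SD, n = 4 each, adjusted p = 0.296), and Ptprc, a pan-leukocyte gene, at 36.7 ± 22.4 and 53.8 ± 24.0 (SD, n = 4 each, adjusted p = 0.547). Of 13 genes of the ureteric bud and collecting duct, 0 were called by limma, 2 lay higher at an unadjusted p under 0.05 and 2 were called as risen in the authors' deposited table. Their median was 0.58 (camera adjusted p = 0.0863, and 0.0446, 0.00724 and 0.00955 without control 1, control 4 and mutant 2), and the adjusted p was 0.895 for all libraries with an estimated correlation. Wnt11 and Upk3a of this list had adjusted p of 0.0851 and 0.0883. Of 3 erythroid genes tested, 0 were called by limma, 2 lay lower at an unadjusted p under 0.05, and 0 were called in the authors' deposited table. Adjusted over the list alone, 0 members of these lists other than Plvap were called.

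The libraries of a group also differed from each other in these markers. In control 3 the median deviation from the group mean was -1.35 for the maturing tubule, -1.51 for the ureteric bud and collecting duct, -0.91 for endothelium and -0.48 for stroma. In mutant 2 it was -0.64, -0.77, -0.14 and -0.59. The nephron progenitor list deviated by 0.01 and 0.04 in these libraries. Xist, expressed from the inactive X chromosome of females, was at 8.84 in control 2 and 51.9 in mutant 2 and between 60017 and 111673 normalised reads in the other 6 libraries, which also held Y-linked reads.

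**Figure D3:**
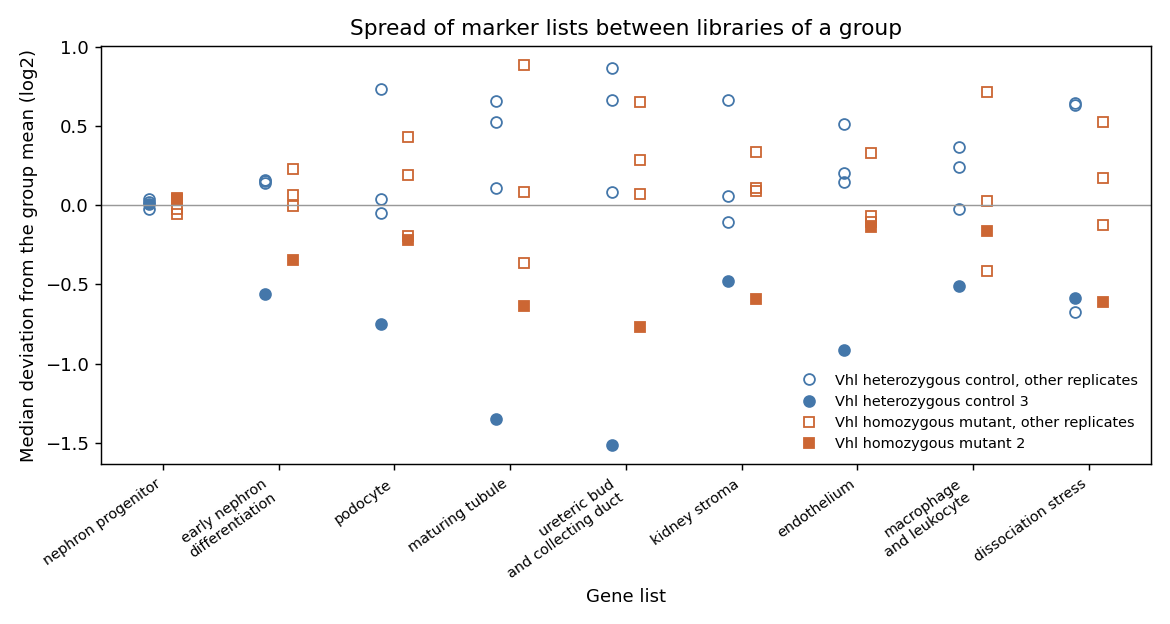
Median deviation of each marker list from the mean of its group (log2), per library, with control 3 and mutant 2 filled. Control 3 reaches -1.51 for the ureteric bud and collecting duct, while the nephron progenitor list stays near 0 in each library.

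Signalling and growth lists gave few calls. Among 12 genes of the canonical Wnt response the transcription factor Sp5 rose 1.44-fold, from 494 ± 21.5 to 716 ± 92.7 (SD, n = 4 each, adjusted p = 0.00564), and Tcf7 fell by 0.24 (adjusted p = 0.0287). Tcf7 kept its call only without control 1 or mutant 1 (adjusted p up to 0.0988 otherwise). The other 10 were not called, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.56). Nkd1 and Ccnd1 had adjusted p of 0.0739 and 0.254. Among 11 genes of the Notch pathway 0 rose, 2 fell and 9 were not called by limma. At an unadjusted p under 0.05, 0 lay higher and 3 lower, as in the authors' deposited table and when adjusted over the list alone (camera adjusted p = 0.165). Lfng, which modifies Notch receptors, fell by 0.45 (adjusted p = 0.0307), and Nrarp, a feedback inhibitor of the pathway, fell by 0.58 (adjusted p = 0.0408). Lfng lost its call without control 2, control 4, mutant 1, mutant 2 or mutant 4 (adjusted p up to 0.0874), and Nrarp kept it only without control 3 or mutant 1 (up to 0.124 otherwise). Notch1 and Rbpj had adjusted p of 0.0819 and 0.409.

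Of 32 cell cycle genes, 0 rose, 1 fell and 31 were not called by limma, also when adjusted over the list alone. At an unadjusted p under 0.05, 1 lay higher and 3 lower, and the authors' deposited table called 0 and 2. Cyclin E1 (Ccne1) fell by 0.39, from 1690 ± 147 to 1288 ± 142 (SD, n = 4 each, adjusted p = 0.0203), a call lost without control 2, control 3 or control 4 (adjusted p up to 0.062). Rrm2, Cdt1 and Cenpf had adjusted p of 0.0544, 0.11 and 0.154. The list's camera adjusted p was 0.119, and it was 0.0163 without control 1 and 0.0474 without control 2, and the full fit gave an adjusted p of 0.895 with an estimated correlation. Among 16 p53 targets 2 rose, 2 fell and 12 were not called, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.748). The cell cycle inhibitor Cdkn1a rose 1.67-fold, from 1529 ± 212 to 2542 ± 194 (SD, n = 4 each, adjusted p = 5.58e-04). Tnfrsf10b rose 1.25-fold (adjusted p = 0.0482), Sesn1 fell by 0.30 and Aen fell by 0.27. Tnfrsf10b kept its call only without control 3 (adjusted p up to 0.141 otherwise), Sesn1 lost it without control 4 (0.065), and Aen lost it without control 2, 3 or 4 or mutant 3 or 4 (up to 0.099).

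Of 16 members of the integrated stress response 2 rose, 2 fell and 12 were not called, with the same numbers adjusted over the list alone. The camera adjusted p was 0.165, and it was 0.0446 without control 1, and the full fit gave an adjusted p of 0.895 with an estimated correlation. Shmt2, of mitochondrial one-carbon metabolism, rose 2.17-fold, from 4007 ± 295 to 8720 ± 675 (SD, n = 4 each, adjusted p = 1.55e-06), with the overlap with Ndufa4l2 given above. The pseudokinase gene Trib3 rose 3.28-fold, from 15.6 ± 5.42 to 52.3 ± 13.8 (SD, n = 4 each, adjusted p = 0.00341). The amino acid transporter Slc7a5 fell by 0.44 (adjusted p = 0.00171), and Mthfd2 fell by 0.38 (adjusted p = 0.0169), a call lost without control 2, control 4 or mutant 3 (adjusted p up to 0.0614). Of 18 immediate early and heat shock genes, known to respond to tissue dissociation, 1 rose, 0 fell and 17 were not called by limma, also at an unadjusted p under 0.05, in the authors' deposited table and adjusted over the list alone. The risen gene was Ier3, 7.22-fold higher, from 223 ± 141 to 1419 ± 262 (SD, n = 4 each, adjusted p = 0.0073). Jun, Fosb and Dnajb1 had adjusted p of 0.326, 0.404 and 0.358. The list's camera adjusted p was 0.0863, and it was 0.00248, 0.00377 and 0.00802 without control 2, control 4 and mutant 2, and the full fit gave an adjusted p of 0.895 with an estimated correlation. Its median deviation was -0.68, 0.63, -0.58 and 0.65 in controls 1 to 4 and 0.52, -0.61, 0.17 and -0.13 in mutants 1 to 4.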

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

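All tests of explanations in this part were chosen after the result was seen. In each group of 4 libraries, the gap between the highest or lowest value and its nearest neighbour was divided by the range of the group. This passed Dixon's critical value for 4 samples in 15 of 270 groups, against 13.5 by chance (1 in 20).

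Control 3 and mutant 2 had the lowest levels of markers of other cell types in their groups. The mean level of these markers over 6 lists was 6.905 (log2) in control 3, against 8.158 to 8.415 in the other controls, and 7.494 in mutant 2, against 7.726 to 8.573 in the other mutants, a gap that did not pass the critical value. Sequencing depth had 2 tests set once the values were seen. The side of the group mean on which the totals lay was dropped as too small an offset. The score gap to the library nearest in depth was -1.35 in control 3, 0.42 M reads apart (SD of the other controls 0.13). It was -1.079 in mutant 2, 1.42 M reads apart (SD of the other mutants 0.43). Picking the lowest libraries fixed the sign of these gaps and favoured a large size, so they cannot decide whether depth was a cause. Control 3 had the lowest total of the controls (41.2 M) and mutant 2 the highest of the mutants (46.5 M). Depth therefore stays open. The sex of the embryos was argued against as a cause shared by both libraries, because Xist was at 65425 normalised reads in control 3 and 51.9 in mutant 2. For mutant 2 alone sex stays open, since Xist was at 60017 to 111673 in the other mutants. Fewer cells of other kidney types stays open: in 11 of 12 places (6 lists in both libraries) the list median was the lowest of its group, but the libraries were picked by these markers, so the count does not bear on the cause.

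The early nephron differentiation list also had its outlying library in control 3, with a median deviation of -0.56 (0.137 to 0.156 in the other controls). In control 3 the endothelial gene Sox17 was at 15.65 normalised reads (36.88 to 37.47 in the other controls) and the erythroid gene Alas2 at 109.6 (69.87 to 75.89). In mutant 2 the stromal genes Tcf21 and Meis1 were at 1898 (2286 to 2354 in the other mutants) and 979.2 (1345 to 1402). The endothelial list had a median deviation of 0.331 in mutant 1 (-0.138 to -0.068 in the other mutants).

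Control 1 had 4 outlying values, and each was lower than in the other controls. Idh2 was at 12196 (13751 to 13971), Cs at 10511 (11958 to 12169), Mthfd2 at 1273 (1614 to 1649) and Aldh1a2 at 33683 (36517 to 37018). Among the mutants, Hif3a was at 1471 in mutant 4 (1386 to 1397 in the others), Fcgbp at 406.3 in mutant 1 (475.1 to 486.1) and Rgs11 at 1071 in mutant 3 (859.1 to 873.5). The p53 list had a median deviation of 0.074 in mutant 3 (-0.02 to -0.005 in the others).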

How the results depend on the processing

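Alternatives chosen after seeing the data were the values as deposited, the other added constants of 0.5 and 5, the authors' deposited test, leaving out control 3 with mutant 2 or control 2 with mutant 2, and the other-cell score as a covariate. The size factor scaling that had been planned as an alternative became the scaling used, so TMM took its place, and a planned fit with a surrogate variable was not run. Vhl kept its call and direction under each alternative. Of 63 called genes among the 113 named, 26 kept their call under each alternative, 45 under each except the test against a fold of 1.5, and 0 turned direction. Of 2705 values of named genes under alternatives, 2442 stayed on their side of the threshold in the same direction, 175 lost a call, 64 gained one and 24 changed sign. TMM, upper-quartile scaling, no filter, a minimum of 1 CPM, the constants 0.5 and 5 and limma-voom gave between 1156 and 1362 called genes, and the covariate gave 1621. The depth, from 37.3 M (mega) reads upwards, limits mainly genes near the minimum of 10 normalised reads. Except where a reason is given, the cause was not tested.

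The count of 1297 called genes (831 risen, 466 fallen) became 697 (537, 160) with the values as deposited, which keep the second division and its spread between libraries. It became 2488 (1387, 1101) with limma-voom with quality weights and 141 (137, 4) when tested against a fold of 1.5, which asks for larger changes and left 138 with an absolute log2 fold change of at least 1. It became 754 (535, 219) without control 3 and mutant 2 and 654 (482, 172) without control 2 and mutant 2, both with fewer samples, and shared 713 and 637 genes with the full set. The authors' deposited test had 810 fallen genes. Leaving out each library in turn gave 771 (without mutant 4) to 1569 (without control 1) called genes, 539 to 917 risen and 230 to 652 fallen. Called list members numbered 112 with quality weights and 35 when tested against 1.5.

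The replicate numbers were not taken to pair the samples, which would have needed a correlation over 0.1 in each same-numbered pair. Same-numbered libraries deviated from their group means with correlations across genes of 0.213, -0.143, -0.144 and 0.063, and control 3 correlated best with mutant 2 (0.57). Low correlations do not exclude a pairing, and control 2 and mutant 2, the libraries with almost no Xist reads, share a number. With the replicate number as a block the count was 766 (550 risen, 216 fallen), 749 of them shared, and the maturing tubule list turned direction with an adjusted p of 0.951.

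The lists called by camera numbered 4, 2 with an estimated correlation, 2 with fry, 7 with the values as deposited, 7 without control 2 and mutant 2, and 4 to 8 with 1 library left out (8 without control 3). The citrate cycle list had an adjusted p of 0.895 with an estimated correlation and 0.257 with fry, and the oxidative phosphorylation list 0.895 and 0.534. Without control 2 and mutant 2, the direction turned for early nephron differentiation (0.493), stroma (0.288) and macrophages (0.728), and without control 3 and mutant 2 for the maturing tubule (0.253) and endothelium (0.253). With 1 library left out, adjusted p ranged from 0.0362 (without mutant 3) to 0.232 for nephron progenitors, 0.0144 (without control 3) to 0.872 for early differentiation, 0.0376 (without control 3) to 0.972 for the maturing tubule, 0.12 to 0.946 for stroma, 0.114 to 0.782 for endothelium and 0.119 to 0.963 for macrophages. The direction turned without control 3 for the maturing tubule (0.0376) and endothelium (0.114), without control 1 for stroma (0.55), without mutant 1 for the maturing tubule (0.3) and endothelium (0.782), without mutant 2 for early differentiation (0.869) and stroma (0.417), and without mutant 4 for macrophages (0.958).

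The genes that changed sign were not called in the fit of all libraries or under the alternative. Without control 2 and mutant 2, log2 fold changes were 0.0089 for Epas1, 0.1253 for Hnf4a, 0.111 for Wnt4 and 0.0559 for Lhx1. Without control 3 and mutant 2 they were -0.1065 for Umod, -0.0194 for Sox17 and 0.0218 for Wnt4. With quality weights they were -0.1447 for Umod, -0.0758 for Alas2 and 0.0028 for Wnt4, and with TMM -0.0043 for Alas2. With 1 library left out they ranged from -0.3567 to 0.0185 for Epas1, -0.235 to 0.4979 for Umod, -0.0029 to 0.4162 for Acta2, -0.1708 to 0.1606 for Alas2, -0.0806 to 0.0557 for Wnt4 and -0.3865 to 0.0087 for Lhx1.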

Other observations

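The genes and lists of this part, and all of its tests, were chosen after their values were seen. Camera p-values of its lists are therefore given as description, since the choice by itself favours small values. The mutant libraries had higher levels of genes that present antigen on MHC class II. Of 10 tested members, 9 rose and 0 fell by limma, the same numbers as at an unadjusted p under 0.05 and in the authors' deposited table, and the median log2 fold change was 1.02 (camera adjusted p = 2.78e-13, adjusted p = 0.00214 with an estimated correlation). The invariant chain gene Cd74 rose 4.70-fold, from 141 ± 21.3 to 663 ± 53.4 normalised reads (SD, n = 4 each, adjusted p = 2.77e-07), and H2-Ab1 rose 4.47-fold, from 516 ± 43.5 to 2318 ± 295 (SD, n = 4 each, adjusted p = 4.22e-08). Ciita, the transcriptional activator of these genes, rose 1.93-fold, from 190 ± 26.3 to 365 ± 21.5 (SD, n = 4 each, adjusted p = 2.81e-04). H2-Oa was not called (log2 fold change -0.08). Of 7 tested genes of peptide loading on MHC class I, 0 were called by limma, 0 had an unadjusted p under 0.05 and 0 were called in the authors' deposited table (camera adjusted p = 0.967), with B2m at 905 ± 94.1 and 857 ± 110 (SD, n = 4 each). Of the class I heavy chain genes looked at, H2-K1 rose 2.46-fold (adjusted p = 0.00271) and H2-Q4 rose 1.60-fold (adjusted p = 2.54e-04), and H2-D1 was not called (log2 fold change 0.24).

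Genes of the circadian clock were the other group seen. Of 19 tested members 10 rose and 0 fell by limma (15 and 0 at an unadjusted p under 0.05, 11 and 0 in the authors' deposited table), with a median log2 fold change of 0.34 (camera adjusted p = 7.62e-13, adjusted p = 0.00214 with an estimated correlation). Rora and Bhlhe40 of this group are also in the HIF target list, and Ciart is among the largest rises given above. Beside Ciart, the repressors Bhlhe41 and Bhlhe40 rose by 3.33 and 2.29 on the log2 scale, Nfil3 rose 1.67-fold, Per2 1.46-fold and Tef 1.41-fold. Clock was at 1503 ± 140 and 1502 ± 176 (SD, n = 4 each, adjusted p = 0.988), and Nr1d1 at 527 ± 51.1 and 529 ± 23.3 (SD, n = 4 each, adjusted p = 0.961). The time of day at which the embryos were collected is not given in the sources used here. The deubiquitinase gene Tnfaip3 rose 4.60-fold, from 147 ± 24.3 to 675 ± 46.3 (SD, n = 4 each, adjusted p = 4.55e-07), and Maf fell by 0.76, from 1549 ± 89.9 to 922 ± 153 (SD, n = 4 each, adjusted p = 0.00116).

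Macrophages in the mutant libraries were argued against, because the macrophage and leukocyte list had a median log2 fold change of -0.14 with 0 members called by limma, also at an unadjusted p under 0.05 and in the authors' deposited table. Other leukocytes stay open, since the pan-leukocyte gene Ptprc had a log2 fold change of 0.788 (SE 0.68) and was not called, while Coro1a and Laptm5, also looked at after the fit, had -0.0079 and -0.0757. For the H2 genes on chromosome 17, of which 7 of 8 tested class II members rose, as did H2-K1 and H2-Q4, another H2 haplotype in the mutants and a change in transcription cannot be told apart, since the table holds no reads by allele. Cd74 and Ciita lie on chromosomes 18 and 16. A rise of class II transcription in the progenitor cells is a hypothesis that stays open.

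Adamts13 had the largest rise of the named genes, and reads from a neighbouring gene might raise its count. The gene lies on chromosome 2 from 26973416 to 27009628, and 5 other tested genes lie within 50 kb. Their largest log2 fold change was 0.215, that of Cacfd1, which starts 298 bases after the end of Adamts13 and was not called (adjusted p = 0.062). This argues against that explanation, and a rise of Adamts13 transcripts in the mutant cells stays as a hypothesis.

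Other splits of the same libraries were tested for the number of called genes. Of the 35 splits of the 8 libraries into 4 and 4, only the real split gave 1297 called genes, and the highest of the other splits gave 1. The other splits mix mutants with controls, which widens the spread within each side. Their low counts therefore do not measure what chance gives, and chance is not excluded for this count. A share of 1 in 35 is the smallest that the design allows.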
